A study of Homo sapiens with 4 samples.

How the data were processed

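The series holds 4 libraries from 1 pooled CRISPR knockout screen in RPMI-8226 cells. Per the labels, cells were infected with sublibrary A or B of GeCKOv2, selected with puromycin for 72 h from 24 h after infection and treated with interleukin-6, and guide cassettes were amplified from genomic DNA taken at a coverage above 500 cells. The design text gives 6 guides for each of 19050 genes and 4 for each of 1864 microRNAs. Sorted cells were the top 5% for CD38, and the controls were not sorted. The samples were grouped by these labels, with the sublibrary as the replicate. Each guide thus has 1 sorted and 1 unsorted value, and the different guides of a gene and the 2 infections are the repeated measurements, so that p-values describe these libraries and not new infections.

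The authors' deposited guide tables give a normalized count per guide, a signal scaled by 1 factor per library, made with MAGeCK per the submitters' processing notes (version not given in the sources used here). In every library 100% of values were whole multiples, within 0.01, of a step (0.991 in unsorted A, 1.01 in sorted A, 0.954 in unsorted B and 1.05 in sorted B), so that read numbers could be recovered. An automatic test of this accepted only the sorted libraries, since the step of unsorted A lies too near 1 and unsorted B holds too few low values for it. The authors' deposited comparison tables give, per the file headers, a log2 fold change, a score, p-values and an FDR per gene and per guide for sorted against unsorted cells. These were made from both sublibraries together. The combined guide table lacks 1358 guides of sublibrary B, 1000 of them non-targeting. Non-targeting values there were 0.983 of the sum of A and B (median, after scaling), so guides of shared sequence appear to have been added up in it. The combined tables were used only for the comparison with them.

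From the normalized counts, log2(count + 1) of sorted minus unsorted was taken per guide and centred on the median guide of its sublibrary, so fold changes are on this scale and understate those of rare guides. Guides with a mean of both values under 20 were left out. The values were standardised within 20 bins of mean abundance and ranked within the sublibrary, and the ranks of the guides of a gene were combined by robust rank aggregation (alpha 0.25), one-sided in each direction. The null came from 4000000 random draws of ranks for each number of guides. It takes the guides of a gene as independent, so shifts shared by neighbouring genes are not part of it. The p-values were adjusted by Benjamini-Hochberg over 18747 genes with 3 or more guides, and apart from these over 1690 microRNAs. The threshold was an FDR of 0.05. The 6 guides of sublibrary A and 3 of sublibrary B under a symbol that reads as a date were left out, which was decided after the files were seen.

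Lists of genes were fixed before the data were examined, and each list's median was placed among 10000 random lists of equal size matched on mean unsorted abundance. Correlations used 100000 permutations. Core fitness guides were compared without a filter on low values. The genes named in the text follow a rule set before the data were examined: CD38, IL6 and 8 genes of its receptor pathway, the 12 genes with the lowest enrichment p and the 8 with the lowest depletion p, the 2 leading microRNAs in each direction with hsa-mir-140 and hsa-mir-708, the 2 leading members of each list that stood apart or held a gene past the FDR, and the authors' 5 highest-ranked targets in each direction. Some results that this rule would name are not reported here.

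For gene order, symbols were matched to a RefSeq gene table of GRCh38.p14 by symbol or by a synonym of 1 gene, which placed 18465 of the 18747 genes. The files name no build, so only the order of neighbours was used. Means over windows of 51 genes (values limited to the 1st and 99th percentile) were set against the highest and lowest windows in each of 1000 permutations of gene order.

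Alternatives fixed in advance were other pseudocounts, filters, rankings, alpha, minimum guide numbers and centring, each sublibrary alone, each gene without its strongest guide, a mean score against random guide sets, limma on guide values, and edgeR's quasi-likelihood test on the recovered reads summed per gene, with and without the sublibrary as a block. Centring on the non-targeting guides cannot move ranks within a sublibrary. A correction for neighbouring genes and runs without chromosome 19 were added after the data were examined.

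The methods were tried on simulated data made from these libraries with gene labels shuffled and 200 of 18747 genes changed. Every guide of a changed gene was given the same fold. Guides that act unequally were not simulated, so the shares recovered may be too high for the screen. For the enrichment and depletion comparison, rank aggregation recovered 44.1%, 90.9% and 100% of genes raised 1.5-, 2- and 3-fold, and 21.2%, 79.4% and 100% of genes lowered by as much, with 3 false calls. edgeR with the block recovered 100% of 2-fold raised genes and without it none, and limma recovered 72.7%. A simulated stretch of 369 genes shifted by 0.2 was found as 1 stretch of 406 genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, were used.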

Results

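The screen measured which gene knockouts shifted RPMI-8226 cells into the fraction with the most CD38 at the cell surface. RPMI-8226 is an established human multiple myeloma cell line, and CD38 is a surface glycoprotein of plasma cells that breaks down NAD and is the target of therapeutic antibodies. The cells were infected with the GeCKOv2 library, a pool of lentiviral vectors in which each vector carries 1 guide RNA for the Cas9 nuclease. They were treated with interleukin-6 at 1 ng/ml for 72 h, and the 5% of cells with the highest CD38 were sorted. Cells were infected with sublibrary A or sublibrary B of the library, and each infection gave 1 sorted and 1 unsorted library, so that 4 libraries were compared. The tables held 111976 guides against 18914 genes, 6834 guides against 1795 microRNAs (sublibrary A only) and the same 1000 non-targeting guides in each sublibrary.

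The libraries held 44171493 reads in unsorted A, 44209405 in sorted A, 54993582 in unsorted B and 50538975 in sorted B. The median guide had 606 reads in unsorted A, 593 in sorted A, 839 in unsorted B and 762 in sorted B. No read was found for 0.0125% of guides in unsorted A (exact 95% interval 0.00540% to 0.0247%), against 0.421% in sorted A (0.372% to 0.474%). The shares in sublibrary B were 0.0141% unsorted (0.00607% to 0.0277%) and 0.135% sorted (0.107% to 0.169%). These intervals cover counting error only. The Gini index of reads over the guides of a library, where 0 is even, was 0.354 in both unsorted libraries, 0.380 in sorted A and 0.370 in sorted B. Guide log2 fold changes, sorted over unsorted, had an SD of 0.67 in A and 0.46 in B.

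The gene that the cells were sorted on was checked first. Guides against CD38 were depleted from the CD38-high cells, with a mean log2 fold change of -1.79 ± 1.01 (SD, n = 6 guides), which is 0.289 of their unsorted level. All 6 guides lay below 0. The strongest went from 828 normalized counts in unsorted cells to 96.3 in sorted cells and the weakest from 716 to 561. The means were -2.01 for the 3 guides of sublibrary A and -1.57 for the 3 of sublibrary B. CD38 was the 1 gene of 18747 past an FDR of 0.05 for depletion in the rank aggregation (adjusted p = 0.00469, null of randomly drawn ranks). Its unadjusted p of 2.5e-07 was the smallest that 4000000 draws can give. For enrichment, JAK1, SWSAP1 and hsa-mir-1181 (below) reached the same floor, so adjusted p-values do not rank these targets against each other. With sublibrary B alone it did not pass.

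No other gene passed for depletion. The next lowest depletion p-values belonged to NAA38, RMDN2, PDXP, AIFM2, MNT, PIK3IP1 and OR52W1. Their adjusted p-values lay between 0.347 for NAA38 and 0.548 for the rest. NAA38, a symbol that the gene table also gives as an older name of LSM8, had a mean log2 fold change of -0.54 ± 0.49 (SD, n = 6 guides; -0.76 in A and -0.31 in B), MNT, which encodes a MAX-binding repressor, -0.63 ± 0.45, and PIK3IP1, an inhibitor of PI3-kinase, -0.62 ± 0.49. PDXP, pyridoxal phosphatase, had -0.74 ± 0.78, with a median guide at -0.40. A few guides carried the other means, 2 for RMDN2 (mean -1.90, median -0.59) and for AIFM2 (mean -1.98, median -0.44; -3.73 in A and -0.23 in B) and 1 for the olfactory receptor gene OR52W1 (mean -1.22, median -0.11; -2.43 in A and -0.01 in B).

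Guides against 14 genes were enriched in the CD38-high cells at an FDR of 0.05. JAK1, the kinase bound to the interleukin-6 receptor chain gp130, had a mean log2 fold change of 0.82 ± 0.70 (SD, n = 6 guides; 1.77-fold; adjusted p = 0.00234). STAT3, the transcription factor that this kinase activates, had 0.71 ± 0.69 (n = 6; 1.64-fold; adjusted p = 0.00352). ARID1A, a DNA-binding subunit of the SWI/SNF chromatin remodelling complex, had 0.95 ± 0.34 (n = 6; 1.94-fold; adjusted p = 0.00312). Of 6 guides each, 5 were above 0 for JAK1, 4 for STAT3 and 6 for ARID1A. The strongest STAT3 guide went from 1078 to 3249 normalized counts and the strongest JAK1 guide from 495 to 1426.

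The other 11 enriched genes all lay on chromosome 19, within a single stretch of 488 neighbouring tested genes that runs from TLE2 to CCNE1. SWSAP1, which encodes a DNA repair protein, had a mean log2 fold change of 0.96 ± 0.37 (SD, n = 6 guides) with all 6 guides above 0, and the erythroid transcription factor gene KLF1 had 0.91 ± 0.15, also with 6 of 6. DAND5 had 0.84 ± 0.44, STX10, a syntaxin of the Golgi, 0.83 ± 0.61, and CCDC130, named YJU2B in current annotation, 0.77 ± 0.29. GTPBP3 had 0.68 ± 0.52, the erythropoietin receptor gene EPOR 0.68 ± 0.22, C19orf38 0.65 ± 0.46 and DNASE2, the lysosomal nuclease, 0.63 ± 0.46. Means differed between sublibraries A and B for DNASE2 (0.98 and 0.28), GTPBP3 (0.99 and 0.37) and STX10 (0.49 and 1.17). The list was completed by RTBDN (0.62 ± 0.48) and CAPS (0.59 ± 0.52), named here after their values were seen. SWSAP1 and EPOR were direct neighbours among the tested genes, and so were DNASE2 and KLF1.

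Genes of the stretch were shifted as a group. Their gene means had a median of 0.18 in sublibrary A and 0.16 in sublibrary B, and 76.2% of them were above 0. Windows of 51 neighbouring genes within the stretch reached a mean of 0.27 around CCDC130, where 95% of 1000 permutations of gene order stayed below 0.08 in every window of the genome. Genes on the rest of chromosome 19, from URI1 to MZF1, had a median of -0.08. ARID1A lay in a smaller stretch of 64 genes on chromosome 1, from IL22RA1 to IFI6, with a median of 0.09. The highest window of that stretch, 0.0820, barely passed the bound of 0.0813. No stretch found in either sublibrary alone overlapped it. JAK1, STAT3 and CD38 lay in no such stretch.

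**Figure D1:**
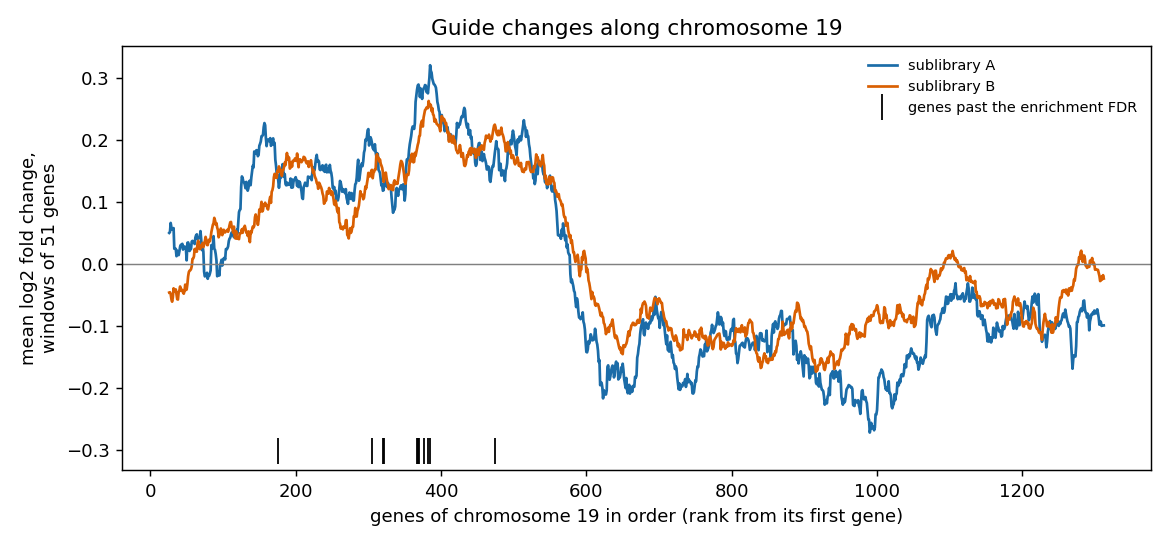
Mean log2 fold change (CD38-high over unsorted) in windows of 51 neighbouring genes along chromosome 19, against gene order, for sublibrary A (blue) and B (orange). Black ticks mark the 11 genes of this chromosome past the enrichment FDR of 0.05. Both curves are above 0 around all of the ticks, with a peak near CCDC130, and mostly below 0 in the later genes.

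When each guide was set against the median of the 50 nearest targeted genes, 4 of the 14 genes remained past the FDR. JAK1 (0.75, adjusted p = 0.00469), STAT3 (0.68, adjusted p = 0.00469), ARID1A (0.87, adjusted p = 0.00586) and SWSAP1 (0.76, adjusted p = 0.00469) passed in that rank aggregation. They were joined by NRDE2 on chromosome 14 (0.28 ± 0.72, adjusted p = 0.0356, with 0.05 in A and 0.41 in B before the correction). NRDE2 is named here after its values were seen. KLF1 had a mean of 0.61 ± 0.15 after the correction, with an adjusted p of 0.390, and the other 9 genes that no longer passed had means from 0.33 (DNASE2) to 0.50 (DAND5). This correction was chosen after the data were examined. The ranks of raw log2 fold changes called 4 genes, which left out JAK1 and STAT3, and both limma on the guide values and the mean guide score called none as enriched.

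**Figure D2:**
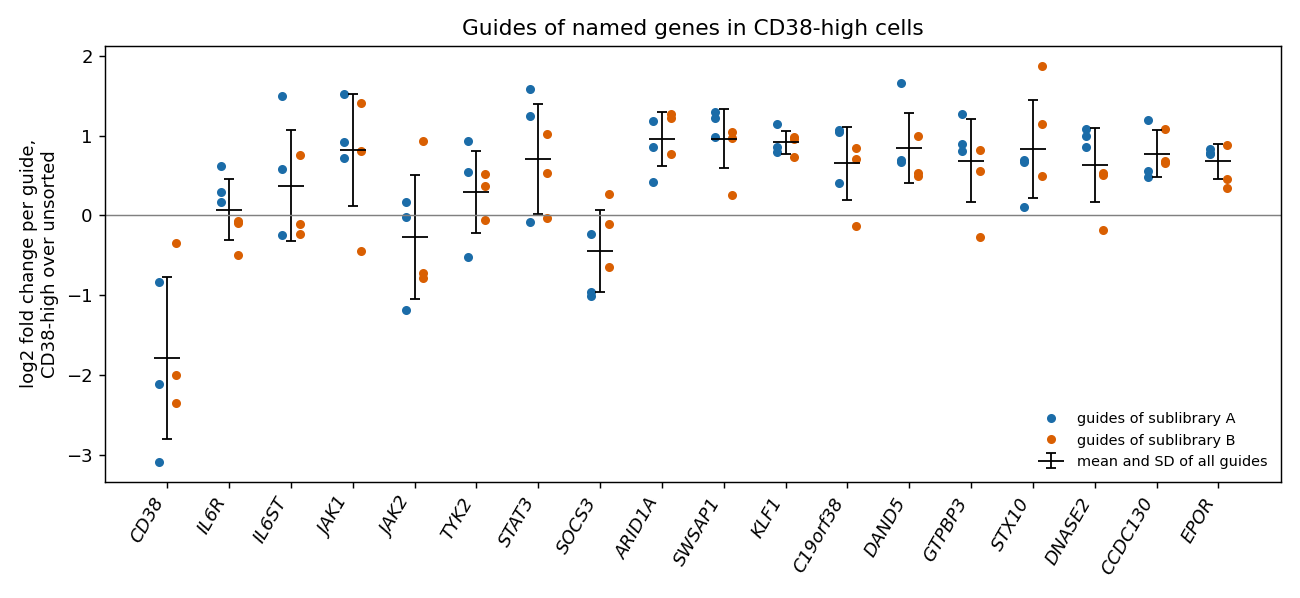
Log2 fold change (CD38-high over unsorted) of each guide of 18 named genes, with guides of sublibrary A in blue and of sublibrary B in orange; black bars give the mean and SD over the 6 guides. All guides of CD38 lie below 0, and 6 of 6 guides lie above 0 for ARID1A, SWSAP1, KLF1, DAND5, STX10, CCDC130 and EPOR.

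Receptor and signalling genes of the interleukin-6 pathway moved up as a list. The 9 genes for the interleukin-6 receptor chains, the JAK kinases and their STATs had a median gene mean of 0.22, at percentile 99.9 of random lists matched on abundance, with 7 members above 0. JAK1 and STAT3 passed the FDR over all genes, and 5 members did so when p-values were adjusted over the list alone. IL6ST, which encodes gp130, had a mean of 0.37 ± 0.70 (SD, n = 6 guides; 0.61 in A and 0.14 in B) and TYK2 0.30 ± 0.51 (0.12 after the correction for neighbours). IL6R had 0.07 ± 0.38, with all 3 guides of sublibrary A above 0 and all 3 of sublibrary B below. JAK2 had -0.27 ± 0.78 and IL6 itself 0.42 ± 0.42 (0.65 in A and 0.18 in B). None of these 5 passed over all genes. TYK2 lies in the chromosome 19 stretch, and after the correction for neighbours the median of the list was 0.12, at percentile 94.6. With sublibrary B alone it was 0.09, at percentile 87.4.

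Among the genes that restrain this pathway, SOCS3, its feedback inhibitor, had a mean log2 fold change of -0.45 ± 0.51 (SD, n = 6 guides, adjusted p = 0.921; -0.74 in A and -0.16 in B) and the phosphatase gene PTPN2 0.15 ± 0.25 (0.04 and 0.26). The 16 negative regulators had a median of -0.03 at percentile 47.3 with no member past the FDR. The 12 interferon receptor and mediator genes had a median of -0.03 at percentile 46.8. JAK1 was their 1 member past the FDR, and JAK1 and TYK2 passed when adjusted over the list alone. STAT2 (-0.12; -0.21 in A and -0.03 in B) and the interferon receptor gene IFNAR2 (-0.11) led that list in the direction of its median. After the correction for neighbours TYK2 had an unadjusted enrichment p of 0.198 in the rank aggregation. Its calls over this list alone and over the interleukin-6 list alone were thus lost.

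In the retinoid and nuclear receptor list of 11 genes the median was 0.16, at percentile 99.6, with 9 members above 0. TLE3, which encodes a transcriptional corepressor, had 0.59 ± 0.70 (SD, n = 6 guides). No member passed over all genes. With sublibrary B alone the median fell inside the central 95% of random lists (0.11, percentile 91.8), as it did with sublibrary A alone (0.10, percentile 87.8) and with the median over all guides of the list (0.06, percentile 81.9). Of the 17 SWI/SNF genes, 12 had means above 0, with a median of 0.06 at percentile 92.5. ARID1A was the member past the FDR, on both adjustments, and the core subunit gene SMARCC1 had 0.46 ± 0.31 with 6 of 6 guides above 0.

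Lists with medians below those of random lists comprised NF-kappa-B signalling, ribosomal proteins, the proteasome and the Mediator complex. The 19 NF-kappa-B genes had a median of -0.23 at percentile 0.01, with 14 members below 0. TRAF2, an adaptor of TNF receptors, had -0.94 ± 1.32 (SD, n = 6 guides), with a median guide at -0.54 and 2 guides above 0. NFKBIA, which encodes the inhibitor of this factor, had -0.58 ± 0.53. Neither passed over all genes, and TRAF2 passed when adjusted over the list alone. The 60 ribosomal protein genes had a median of -0.18, below all 10000 random lists, with 47 members below 0. They were led by RPL13 (-1.07 ± 1.65, with a median guide at -0.57) and RPL18 (-0.63 ± 0.51). The 32 proteasome genes had -0.17 at percentile 0.12, led by PSMC6 (-0.41) and PSMA2 (-0.46; -0.69 in A and -0.24 in B). The 30 Mediator genes had -0.12 at percentile 1.52, led by MED29 (-0.16; -0.44 in A and 0.11 in B) and MED11 (-0.12; 0.30 and -0.54). MED29 lies on chromosome 19 outside the enriched stretch, and its mean was 0.00 after the correction for neighbours. Mediator members CDK8 and MED1 went the other way and passed for enrichment when adjusted over the list alone. RPS28, which lies inside the enriched stretch of chromosome 19, did so among the ribosomal genes. The proteasome median was inside the central 95% with sublibrary A alone (-0.08), and the Mediator median was inside it with either sublibrary alone (-0.07 and -0.06).

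The medians of the remaining lists lay inside the central 95% of random lists. They were -0.10 for plasma cell and B cell transcription factors, where IRF4 passed for depletion when adjusted over the list alone, -0.13 for SAGA and acetyltransferases, -0.10 for histone deacetylases and corepressors, -0.09 for the spliceosome and -0.07 for p53 and cell cycle brakes. For ER translocation, GPI anchor synthesis, PRC2 with its demethylases, DNA methylation, N-glycosylation and PI3K and mTOR signalling they were -0.07, -0.07, -0.05, -0.04, -0.04 and -0.02. For the MLL complexes, RAS and MAPK signalling, endocytosis, cereblon with its ubiquitin ligase and heterochromatin they were 0.01, 0.02, 0.03, 0.03 and 0.04. None of these lists had a member past the FDR over all genes. NAD and adenosine metabolism (-0.06) and plasma cell surface proteins (0.04) each held CD38 as their 1 member past the FDR, on both adjustments. Next to CD38, NAMPT (-0.09; -0.01 in A and -0.16 in B), CD47 (-0.43, with a median guide at 0.38; -0.90 and 0.05) and CD44 (0.21; 0.63 and -0.20) led these lists. Markers of other blood lineages had a median of 0.02 and held KLF1, with LYZ next (0.24; 0.65 in A and -0.18 in B). The 369 olfactory receptor genes, which serve as genes not expected to act in these cells, had a median of -0.01 at percentile 83.7 and no member past the FDR.

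**Figure D3:**
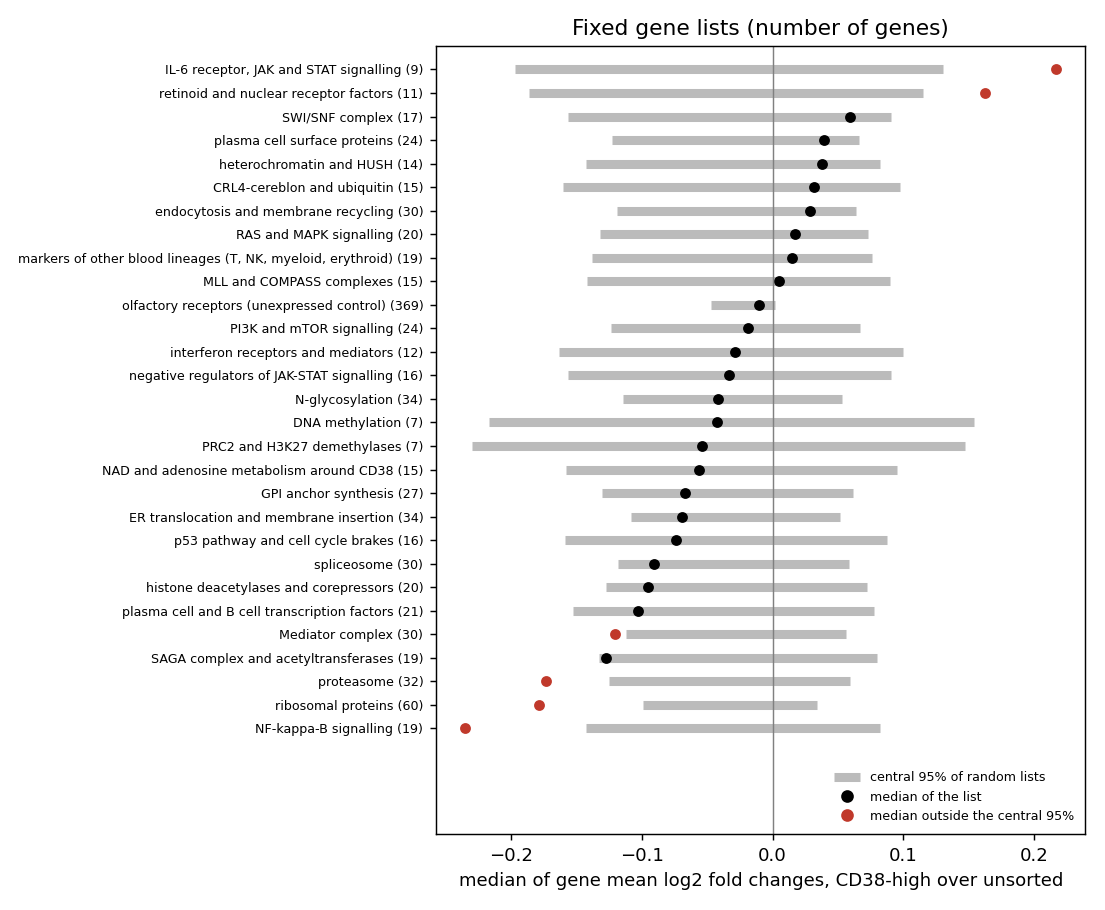
Median of gene mean log2 fold changes (CD38-high over unsorted) for each of 29 gene lists, with the number of genes tested in parentheses. Grey bars span the central 95% of 10000 random lists matched on unsorted abundance, and the 6 red points lie outside it, 2 above and 4 below.

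Guides against 1 of 1690 microRNAs were enriched. The 4 guides of hsa-mir-1181 had a mean log2 fold change of 1.04 ± 0.13 (SD, n = 4 guides, adjusted p = 0.000422 in the rank aggregation). The mean after the correction for neighbours was 0.86 with an adjusted p of 0.0161. This microRNA gene overlaps CDC37 on chromosome 19. Guides against CDC37 had a mean of -0.18 ± 0.41 (SD, n = 6 guides) after the correction for neighbours and did not share the enrichment. The next, hsa-mir-7974, also on chromosome 19, had 0.71 ± 0.23 (adjusted p = 0.117). Guides against 2 microRNAs were depleted, hsa-mir-6859-1 with -1.40 ± 0.77 (0 of 4 guides above 0, adjusted p = 0.0237) and hsa-mir-3195 with -2.72 ± 3.67 (2 of 4 above 0, adjusted p = 0.0414). The gene table lists 4 genes of the hsa-mir-6859 family, and cuts at several sites were not tested. For hsa-mir-3195, 2 guides with 60 and 58 unsorted reads had none after the sort. The others set in advance, hsa-mir-140 (-0.12 ± 0.22) and hsa-mir-708 (-0.01 ± 0.71), did not pass in either direction. With a pseudocount of 20, without a filter, or with a mean of at least 100, 1 microRNA was depleted in place of 2.

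Gene means of sublibraries A and B, which hold different guides of the same genes, were weakly related. Across 18582 genes, which are not independent replicates, Pearson's r was 0.0486 and Spearman's rho 0.0557 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Gene means had the same sign in both for 52.0% of genes. Of 6 genes past the enrichment FDR in A alone (JAK1, STAT3, SWSAP1, C19orf38, DNASE2 and UNC13A), 5 were above 0 in B, and of 4 past it in B alone (ARID1A, STX10, MRPL34 and PTGER1), 3 were above 0 in A. Without the genes of chromosome 19, r was 0.034.

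Non-targeting guides set the background of these values. Their median log2 fold change was 0.00 with an SD of 0.51 in sublibrary A (n = 996) and -0.02 with an SD of 0.43 in B (n = 1000). Gene-targeting guides had an SD of 0.65 in A and 0.46 in B, with Kolmogorov-Smirnov distances from the non-targeting guides of 0.0243 and 0.0554. The central 95% of non-targeting guides ran from -1.08 to 0.90 in A and from -0.86 to 0.62 in B, and the same guide in A and B was not correlated (r = -0.0262, permutation p = 0.408; rho = -0.0415, permutation p = 0.190; adjusted over the 4 correlations of this kind, 0.408 and 0.253).

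Guides against ribosomal protein and proteasome genes, which most cells need, were less abundant than non-targeting guides before the sort. In the unsorted cells, guides against ribosomal protein genes lay -0.32 (log2) from the non-targeting guides, those against proteasome genes -0.33 and those against spliceosome genes -0.05 (0.00 in A and -0.16 in B). All of these together lay at -0.27, with -0.24 in sublibrary A and -0.32 in B. Their 122 genes had a median below the central 95% of random gene lists, at percentile 0.02. The spread of non-targeting guides in the same libraries was 1.06 (SD). Set against olfactory receptor guides the distance was -0.42. The level of each guide in the pool before infection was not used here.

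The authors' deposited table of a MAGeCK comparison of both sublibraries together led with the same genes. Its 5 highest-ranked targets for enrichment were SWSAP1, hsa-mir-1181, ARID1A, KLF1 and STAT3, and it placed JAK1 sixth. It held 14 genes at an FDR under 0.05 for enrichment, of which 11 were among the 14 found here, and the other 3 (UNC13A, SAFB2 and SPDYE2) are named after their values were seen. It held 2 for depletion, CD38 (FDR 0.00495) and RBM14 (FDR 0.0272). Its 5 highest-ranked targets for depletion were CD38, RBM14, TRAF2, NAA38 and hsa-mir-6859-1. RBM14 had a mean log2 fold change of -0.63 ± 0.90 here (SD, n = 5 guides, adjusted p = 0.842 in the rank aggregation), with -1.48 in A and -0.06 in B. Of the 14 enriched genes in the authors' deposited table, 10 were on chromosome 19, and 1 non-targeting guide, treated there as a gene of its own, also passed for enrichment. Of microRNAs, hsa-mir-1181 and hsa-mir-7974 (FDR 0.0366) passed there for enrichment and none for depletion. There hsa-mir-6859-1 had a depletion FDR of 0.264 and hsa-mir-3195 of 0.921. Those FDRs cover 21708 targets of every kind together, whereas microRNAs here were adjusted over 1690, apart from the genes. The FDRs of microRNAs here and there thus cannot be compared directly. The unadjusted depletion p was 1.4e-05 for hsa-mir-6859-1 and 4.9e-05 for hsa-mir-3195 (rank aggregation). NAA38, at 3.7e-05, had an adjusted p of 0.347 over the genes alone. At these p-values neither microRNA would pass an FDR of 0.05 if adjusted together with the genes. Gene fold changes in the authors' deposited table and the median guide values here had a rank correlation of 0.965 across 18747 genes.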

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

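The position correction, the runs without chromosome 19 and the alternatives for microRNAs were chosen after the data were examined. CD38 was called depleted in all but 3 settings, and JAK1, STAT3 and ARID1A enriched together in most. The 14 enriched genes became 4 with raw log2 fold changes, 5 after the position correction, 3 without chromosome 19 (JAK1, STAT3 and ARID1A), 48 at an FDR of 0.25 and 32 with edgeR and the sublibrary as replicate block, all 14 among them. They became 0 with the mean standardised score (1137 at an unadjusted p under 0.05), 0 with limma (406) and 0 with edgeR and no replicate block (3), a fit that also recovered none of the simulated genes. Either sublibrary alone gave 4 to 6. The other settings gave 13 to 20. The 1 depleted gene became 5 with the block (CD38, CHD7, H1F0, LY6E and PRMT5), 2 in the authors' table, 0 with limma (518 at an unadjusted p under 0.05) and 0 with no replicate block (1), and 0 to 1 with either sublibrary alone. Chance alone puts many of the tested genes at an unadjusted p under 0.05, so the counts at that threshold are no signal by themselves. Fewer guides per gene enter with 1 sublibrary, and the cause of the other changes was not tested. The 6 lists outside the random range became 3 to 5 with 1 sublibrary and 6 or 7 otherwise. The 2 depleted microRNAs became 1 with a pseudocount of 20, 1 without a filter and 1 with a mean of at least 100. Core fitness guides lay at -0.42 against olfactory receptor guides in place of -0.27. No called gene mean and no median of a list outside the random range changed sign. The means of 3 targets (KLF1, CCDC130 and hsa-mir-1181) moved by more than their guide SD, under the position correction.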

Other observations

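Some of the tests here were chosen after the results were seen. These were the comparison of parts of chromosome 19 up to CCNE1 and the comparisons of lost guides under 200 reads and within each sublibrary. So were the tests of the stretch found in sublibrary A on values of B, without the genes past an FDR of 0.25 or for olfactory receptors. The other tests here were written down after the called genes were seen to lie on chromosome 19, but before they were run. Outside chromosome 19, the longest depleted stretches lay on chromosome 22: a stretch of 90 genes from IGLL1 to SELM had a median of -0.17 and a stretch of 119 genes from APOL4 to SMDT1 a median of -0.15, and each overlapped a stretch found in sublibrary B alone, the first also one of 67 genes found in A alone. PDXP and PIK3IP1, among the genes with the lowest depletion p, lie on chromosome 22. The median of the neighbours was -0.15 for PDXP and -0.04 for PIK3IP1. After the correction for neighbours the unadjusted depletion p was 0.0645 for PDXP and 0.000401 for PIK3IP1 (rank aggregation). Smaller enriched stretches lay on chromosomes 1, 3, 7 and 12 and depleted ones on chromosomes 8, 10, 14 and 17. At an FDR of 0.25, 31 of the 48 enriched genes were on chromosome 19, and those elsewhere, named here after their values were seen, included the Notch target gene HES1 (0.41 ± 1.03, SD, n = 6 guides) and the Mediator genes MED1 (0.86 ± 2.23) and CDK8 (0.39 ± 0.43), while the Mediator list as a whole had a median below 0.

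The neighbouring enriched genes of chromosome 19 are a first pattern. Without the 31 genes past an FDR of 0.25 the other 457 had a median of 0.148, which decides nothing as the stretch was chosen on these values, but a few acting genes among neighbours that do not move were argued against by the stretch found in sublibrary A, whose other 445 genes had a median of 0.142 in B against an upper bound of 0.00754 for random sets elsewhere. Chance order or a single infection was argued against by the median in B of that whole stretch, 0.160 against a bound of 0.00708. A prior loss of cut cells was argued against by their unsorted abundance, 9.33 (log2) in the stretch and elsewhere with a lower bound of 9.28. That abundance was not set against the pool before infection, so a loss hidden by a higher starting level would not be seen. Of the explanations tested, an effect of cutting the locus whatever the gene remains. Guide sequences were not used here, so base content and cuts at other sites were not tested as regional causes. The 19 olfactory receptor genes of the stretch had a median of 0.195 against a bound of 0.0808. This decides nothing either, as the stretch was chosen on these values. Those of the stretch found in A had a median of 0.132 in B against a bound of 0.110, which goes with this effect by a narrow margin. Part of the enrichment of the 11 genes may thus not come from their products. Whether a cut there removes the outer arm with a gene whose dose matters cannot be told apart from other regional effects. Among 5 equal parts of the genes up to CCNE1, the medians in gene order were 0.02, 0.14, 0.12, 0.24 and 0.17. In this uneven profile the last part lay 0.0511 above the middle part and below the part before it. Only gene order was used, so whether all parts lie on 1 arm was not checked. The inner end of the stretch is not sharp, as it lay at ZNF730 in A alone and at POP4 in B alone. No karyotype or expression data were used here.

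Guides that fell at least 16-fold in the sorted cells are a second pattern. They made up 0.399% of gene guides and 0.812% of microRNA guides in sublibrary A and 0.111% of gene guides in B, together 285 of 111682 gene guides (0.255%), and none of 1996 non-targeting guides, which allows a share of up to 0.185% (exact 95% interval). Random loss alone was argued against by this difference between gene and non-targeting guides (one-sided Fisher's exact p = 0.00638), which rested on A (exact p = 0.0194, and 0.332 in B). Under 200 unsorted reads, 271 of 8302 gene guides and 0 of 157 non-targeting guides were lost (exact p = 0.00574). This adds no separate support, as 271 of the 285 lost gene guides lay there and no non-targeting guide was lost anywhere. Abundance was not matched within that range. The 1996 non-targeting values come from the same 1000 guides in both sublibraries. The lost guides had been rare before the sort, with a median log2 abundance of 6.30 against 9.42 for all guides. Chance loss of rare guides may thus have played a part. Whether harm to the cells before sorting added to it is left open. Gene guides as a whole were not more often under 200 unsorted reads (7.43%) than non-targeting guides (7.87%). The 5 genes with 2 or more lost guides, at the upper bound of 5 for random assignment, were AIFM2, MRPS30, RMDN2, RPS27 and TOP3A; guide sequences were not used here, so cuts at several sites were not tested.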
